A study of Mus musculus with 40 samples.

How the data were processed

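Total RNA from subcutaneous white adipose tissue of 40 male C57BL/6J mice was hybridised to 2-colour Agilent whole-genome arrays, per the labels. All mice had a 3-week adaptation, then a diet of normal to low fat content for 40 weeks, and were fasted for 2 to 4 h before death. Labelling started from 200 ng of RNA. Each animal's own RNA carried Cy5, and the Cy3 channel carried a pool of 5 randomly chosen samples per genotype, per the labels' protocols. All arrays had the same dye orientation, so a dye effect is common to every array and drops out of differences between genotypes. Arrays were grouped by genotype and replicate number from their titles, 10 per genotype, with titles that name no litter, cage or slide.

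One table of values was used, with 38916 probes for each of 40 arrays and 0 missing values. Scanning and feature extraction used Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. The background correction, the probe filter, the normalization and the use made of the reference channel are not given in the sources used here. The deposited values are log2 levels, an inference from their range of 0.0774 to 20.4 and not a stated fact. All 40 arrays have a median of 7.90, so the authors had scaled the deposited values to a common median. Values spread around 7.90 and not around 0, so they were read as levels of the sample channel and not as ratios to the pool. A higher value was taken as more RNA in the sample.

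Probes carry only a feature number, between 5 and 62972. The gene table used here could not be joined to these numbers, so no probe was given a gene name. The tests had been planned per gene, before the data were examined, and were run per probe for this reason. The planned levels of Fgf21 and Ucp1, the tests of marker and pathway gene lists, the test of genes near the Fgf21 locus, and the covariates built from lymphocyte and muscle genes were not analysed here. Genotype labels were therefore not checked against the level of the targeted gene.

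Differences between genotypes were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), with a mean per genotype, all 40 arrays in one fit, 36 residual degrees of freedom, no covariate and no filter on dim probes. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 over all 38916 probes. The planned differences were tested (UCP1tg against WT, FGF21KO against WT, FGF21KO_UCP1tg against FGF21KO, FGF21KO_UCP1tg against UCP1tg) together with the interaction. The difference between FGF21KO_UCP1tg and WT was added after the data had been seen. Probes to be named were to be those with the largest rise and fall past the threshold, those of smallest p for the interaction, and those of smallest p where fewer than 5 passed. This rule was fixed before the data were examined, and it was cut to 2 probes per direction because no probe was given a gene name.

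Principal components were computed from all probes, and scores on the first 4 were compared by two-sided permutation tests with 100000 resamples. The share of the transgene effect kept without FGF21 was estimated from covariances between separate arrays, with a jackknife SE over arrays, and from 20 seeded divisions of the arrays. The fit was tested on simulated data made for UCP1tg against WT over 38916 probes, with 50 probes changed at each size. It recovered 74% of the probes at a log2 change of 0.5, 88% at 1, 100% at 2 and 100% at 3. There were 10 false calls among 191 and 0 calls in a comparison without simulated changes. A simulated share kept of 0.3 was estimated as 0.274. The simulated noise was independent between probes and between arrays, while the real arrays share components. These values therefore check the fit on such noise only, and do not give the error rate or precision in the real data. No pair of arrays held identical values, and pairwise correlations lay between 0.945 and 0.994.

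Alternatives planned before the data were examined were the replicate number as a block, quantile normalization, median centring, removal of the 30% dimmest probes, eBayes with trend and robust options, array weights, fits of only the genotypes compared, and a minimum of 1.5-fold. Those added after the data had been seen were fits without the 10 arrays apart on the first component, with that component as a covariate, with pairs of consecutive replicate numbers as a block, and with each array left out. The division of WT and UCP1tg arrays between the tests of the transgene effect and the interaction was added then as well, as were other assignments of the 30 arrays. A slide block and another background correction were planned but not run, since slide and raw intensities were not used here.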

Results

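Gene expression was profiled in subcutaneous white adipose tissue, a fat depot under the skin, of adult male C57BL/6J mice of 4 genotypes. The genotypes were wild type (WT), a knockout of FGF21 (FGF21KO), a transgene that places UCP1 in skeletal muscle (UCP1tg) and the cross of both (FGF21KO_UCP1tg). UCP1 is a mitochondrial protein that uncouples respiration from ATP synthesis, and FGF21 is a secreted hormone that acts on adipose tissue. Each genotype had 10 arrays, 40 in all, and each array carried 38916 probes. The number of arrays limits the precision, with a median SE of 0.11 for a log2 difference between 2 genotypes. The gene table used here could not be joined to the probes, so probes are given by their feature number and no gene is named. The level of FGF21 itself was therefore not analysed here, and one gene can be measured by several probes.

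The 40 arrays differed along components that did not all follow genotype. The third principal component, with 11.9% of the variance, separated the UCP1tg arrays from the other genotypes. Its mean score was 0.219 ± 0.0688 (SD, n = 10) in UCP1tg, -0.0726 ± 0.125 in WT, -0.128 ± 0.0892 in FGF21KO and -0.0184 ± 0.0687 in FGF21KO_UCP1tg. The margin was narrow, with the lowest UCP1tg array at 0.1197 and the highest FGF21KO_UCP1tg array at 0.1133. The difference between UCP1tg and WT had a two-sided permutation p of 3e-05, or 3e-04 after Benjamini-Hochberg adjustment over 20 tests, 5 comparisons on each of the first 4 components. The third was picked out after its scores had been seen. Between FGF21KO_UCP1tg and UCP1tg the adjusted permutation p was 2e-04, from a raw p of 1e-05 that is the smallest the resampling can give. Between FGF21KO_UCP1tg and FGF21KO it was 0.0499, from a raw p of 0.00748, which lies at the threshold and leaves this difference undecided. FGF21KO did not differ detectably from WT on this component (adjusted permutation p = 0.398). The first component, with 28.3% of the variance, set 10 arrays apart from the other 30. These were 2 arrays of WT, 4 of UCP1tg, 4 of FGF21KO_UCP1tg and 0 of FGF21KO. In these 10 arrays 948 probes were at least 2-fold higher and 42 at least 2-fold lower than in the rest. Smaller differences ran mainly the other way, with 5063 probes higher and 9954 lower by limma and a median log2 difference of -0.10 over all probes. The arrays were picked by these values, so the counts are descriptive.

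**Figure D1:**
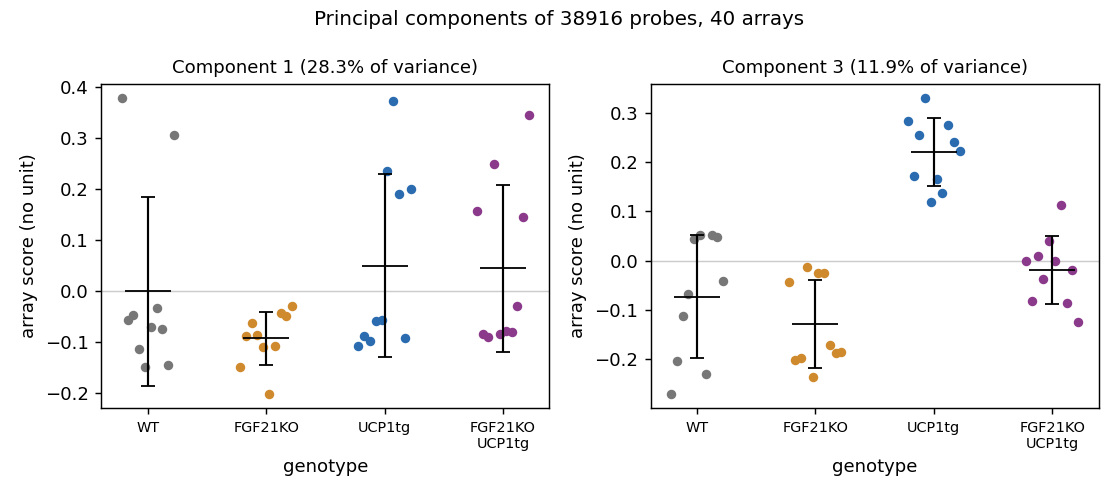
Score of each array (points, 10 per genotype) on the first principal component and on the third (no unit) by genotype; the horizontal line is the mean and the bar the SD. The lowest UCP1tg array scores 0.1197 on the third component and the highest other array, of FGF21KO_UCP1tg, 0.1133. On the first, 10 arrays of WT, UCP1tg and FGF21KO_UCP1tg lie above the rest.

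With FGF21 present, the muscle transgene was accompanied by a broad change in the fat depot. UCP1tg differed from WT at 3216 of 38916 probes, or 8.26%, with 1944 higher and 1272 lower. The rises reached further than the falls. At least 4-fold rises were found at 24 probes and at least 4-fold falls at 0, while 180 probes rose and 82 fell at least 2-fold. Probe 6844 rose from 11.24 ± 2.15 in WT to 15.73 ± 1.51 in UCP1tg (log2 level, mean ± SD, n = 10 each), a log2 fold change of 4.49 ± 0.724 (SE, limma adjusted p = 5.05e-05). Its WT levels ran from 8.92 (WT 1) to 14.36 (WT 8). The WT mean lies in a gap, with no WT array between 10.03 (WT 10) and 12.17 (WT 5). Probe 37215 rose by 3.49 ± 0.396 (limma adjusted p = 1.06e-07).

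Among the probes that fell, probe 48216 went from 14.58 ± 0.697 in WT to 12.61 ± 0.438 in UCP1tg, a log2 fold change of -1.97 ± 0.23 (limma adjusted p = 2.01e-07). Probe 11228 fell by 1.90 ± 0.212 on the log2 scale (limma adjusted p = 9.13e-08). The median change was 0.47 among the probes that rose and -0.51 among those that fell. Of the 3216 probes, 421 had a partner among them with a correlation above 0.95 across arrays once the genotype means were removed. Such partners can be probes of the same gene or genes that vary together, so the number of genes is not known. A fit restricted to the WT and UCP1tg arrays called 1942 probes, the first component as a covariate 5253 and a minimum of 1.5-fold 1113. Without the 10 arrays set apart on the first component the count was 3042, of which 2299 were also called with all arrays in the same direction, and the split moved to 2344 higher and 698 lower.

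**Figure D2:**
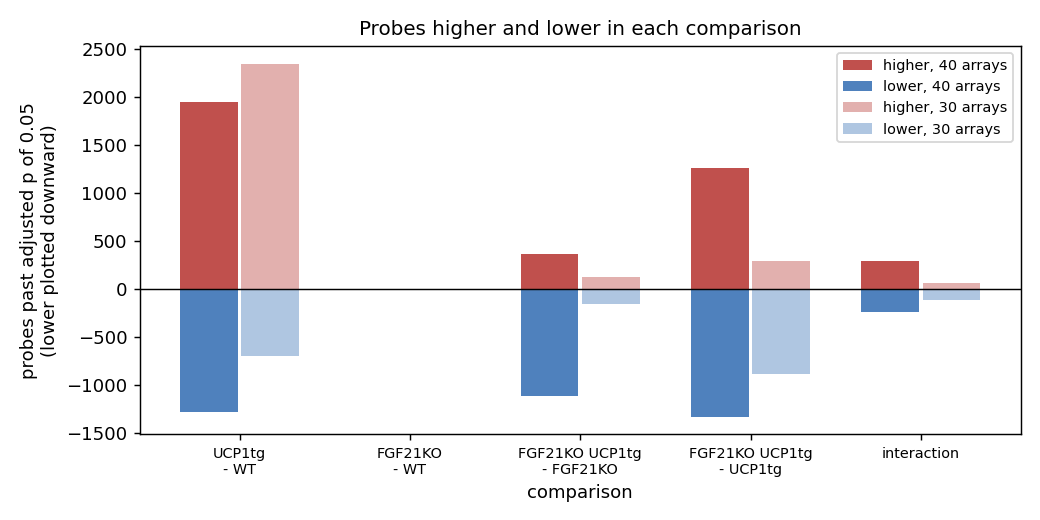
Number of probes past a limma adjusted p of 0.05 that were higher (upward bars) or lower (downward bars) in each comparison, over all 40 arrays (dark) and over 30 arrays without the 10 set apart on the first component (light). UCP1tg against WT gives 3216 probes over 40 arrays and FGF21KO against WT gives 0.

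Loss of FGF21 alone left no probe past the threshold. FGF21KO against WT gave 0 of 38916 probes by limma, with a lowest adjusted p of 0.12, and 3366 probes, or 8.65%, at an unadjusted p under 0.05. The probes with the smallest p included 469, with a log2 difference of 0.51 ± 0.0949 (SE, limma adjusted p = 0.12), and 12339, with 0.62 ± 0.128 (limma adjusted p = 0.136). Probe 41199 stood at 13.61 ± 0.714 in WT and 12.45 ± 0.406 in FGF21KO (SD, n = 10), a log2 difference of -1.16 ± 0.227 (limma adjusted p = 0.136). For probe 37971 the log2 difference was -1.17 ± 0.239 (limma adjusted p = 0.136). After quantile normalization the limma adjusted p was 0.00776 for probes 469 and 41199, 0.0132 for probe 37971 and 0.056 for probe 12339. In the fit without the 10 arrays it was 0.0437 for probes 41199 and 37971, 0.0569 for probe 469 and 0.274 for probe 12339. The count of 0 sits near the threshold, since quantile normalization gave 11 probes, array weights 59, the first component as a covariate 18 and the fit without the 10 arrays 6. Leaving out a single array gave 7 probes without WT 1, 12 without WT 7, 1 without FGF21KO 1, 1 without FGF21KO 6 and 7 without FGF21KO 7.

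In mice without FGF21 the transgene was accompanied by changes at 1481 probes, 365 higher and 1116 lower in FGF21KO_UCP1tg than in FGF21KO. This count was below the 3216 of UCP1tg against WT, but the order was not stable and the difference in counts was not tested. Array weights gave 6437 against 3195, fits of only the genotypes compared gave 2105 against 1942, and at an unadjusted p under 0.05 there were 8445 against 8153. The order held after quantile normalization (1655 against 4416) and without the 10 arrays apart on the first component (284 against 3042). It also held in every fit with a single array left out. With the first component as a covariate the count was 2156 against 5253, with a split of 1111 higher and 1045 lower. With pairs of consecutive replicate numbers as a block it was 2662 against 4273, with 852 higher and 1810 lower. Probe 44673 went from 9.60 ± 1.1 in FGF21KO to 7.31 ± 0.431 in FGF21KO_UCP1tg (log2 level, SD, n = 10), a log2 fold change of -2.30 ± 0.452 (limma adjusted p = 0.00308). Probe 51747 fell by 2.19 ± 0.463 on the log2 scale (limma adjusted p = 0.00588). Probe 39540 rose from 13.62 ± 1.2 to 15.97 ± 0.696, by 2.35 ± 0.546 (SE, limma adjusted p = 0.0121), and probe 17264 rose by 2.34 ± 0.571 (limma adjusted p = 0.0168).

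This comparison set 4 of the 10 arrays apart on the first component against 0 of them. Its log2 fold changes correlated with the difference between those 10 arrays and the rest across probes (Pearson r = 0.559), which are not independent replicates. Without the 10 arrays 284 probes passed, 129 higher and 155 lower, of which 219 were also called in the same direction with all arrays. Removing random arrays in the same numbers per genotype left a median of 238.5 probes over 100 draws. The limma adjusted p was then 0.0779 for probe 39540 and 0.0995 for probe 17264, with log2 fold changes of 2.35 and 2.38. Single arrays also moved the count. It was 2511 without FGF21KO 1, 971 without FGF21KO 3, 548 without FGF21KO 5, 879 without FGF21KO 8, 717 without FGF21KO 9 and 856 without FGF21KO 10. Within FGF21KO_UCP1tg it was 802 without array 1, 705 without 4, 922 without 6, 2330 without 7 and 646 without 10.

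**Figure D3:**
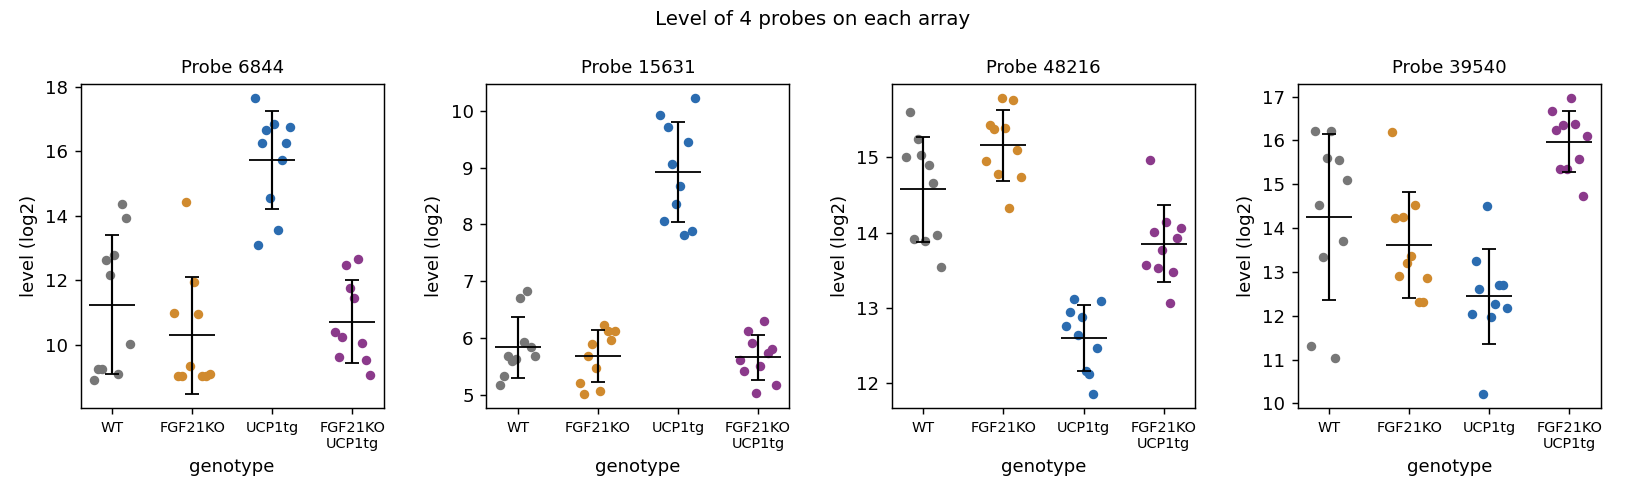
Log2 level of probes 6844, 15631, 48216 and 39540 on each array (points, 10 per genotype), with the mean (horizontal line) and SD (bar). Probes 6844 and 15631 are highest in UCP1tg, probe 48216 is lowest there, and probe 39540 has its lowest mean in UCP1tg (12.44) and its highest in FGF21KO_UCP1tg (15.97).

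Among mice with the transgene, loss of FGF21 changed 2586 probes, 1260 higher and 1326 lower in FGF21KO_UCP1tg than in UCP1tg. The probes that had moved most between UCP1tg and WT were among them. Probe 6844 fell from 15.73 ± 1.51 in UCP1tg to 10.72 ± 1.28 in FGF21KO_UCP1tg (log2 level, SD, n = 10), a log2 fold change of -5.01 ± 0.724 (limma adjusted p = 1.91e-05). Probe 16899 fell by 3.79 ± 0.639 on the log2 scale (limma adjusted p = 0.000155). Probe 17264 rose by 3.58 ± 0.571 (limma adjusted p = 7.02e-05) and probe 39540 by 3.53 ± 0.546 (limma adjusted p = 4.62e-05).

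Of the 1944 probes that rose in UCP1tg against WT, 1013 were lower in FGF21KO_UCP1tg than in UCP1tg. Of the 1272 that fell, 681 were higher. Lists drawn independently would share 66.2 and 41.2 probes. Both comparisons use the UCP1tg arrays, so they share chance values. With the UCP1tg arrays divided, 5 for each comparison, the median overlap over 20 divisions was 325 and 143 probes (lowest 195 and 105). The divided fits called fewer probes, a median of 1827 and 1362.5, so the 66.2 and 41.2 of the full lists are no baseline for them. The direct test of a dependence on FGF21 is the interaction. This comparison gave 1168 probes without the 10 arrays, 291 higher and 877 lower, of which 973 were also called in the same direction with all arrays, and random removals left a median of 718. The first component as a covariate gave 4430 and a minimum of 1.5-fold gave 857.

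Whether the response to the transgene depended on FGF21 was tested as the interaction, the transgene effect without FGF21 minus that with FGF21. The effect differed at 529 probes, with a positive interaction at 288 and a negative one at 241. Probe 15631 had log2 levels of 5.84 ± 0.538 in WT and 8.92 ± 0.881 in UCP1tg, against 5.68 ± 0.46 in FGF21KO and 5.67 ± 0.397 in FGF21KO_UCP1tg (SD, n = 10 each). Its interaction was -3.09 ± 0.361 (SE, limma adjusted p = 4.94e-06). Probe 28910 behaved alike, with means of 6.08, 9.26, 5.74 and 5.95 in the same order and an interaction of -2.97 ± 0.369 (limma adjusted p = 1.17e-05). Its levels followed those of probe 15631 from array to array. So did those within the pairs 6844 and 37215, 48216 and 11228, 39540 and 17264, 44673 and 51747, and 41199 and 37971. Within genotypes, probe 16899 also varied with probe 6844, and probe 19579 with probe 39540. Probes that vary together may measure the same gene or genes that move together, and are not separate evidence. The positive interactions of smallest p were those of probe 19579, at 2.17 ± 0.302 (limma adjusted p = 5.48e-05), and of probe 36914, at 1.11 ± 0.174 (limma adjusted p = 0.000382).

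The interaction passed at 210 of the 1944 probes that rose in UCP1tg against WT (10.8%) and at 185 of the 1272 that fell (14.5%). A probe without this call need not have responded alike in both backgrounds. Of the 529 interaction probes, 395 had also changed between UCP1tg and WT, and at all 395 the interaction ran against that change. Both values use the same arrays, which favours opposite signs. With the WT and UCP1tg arrays divided between the 2 tests, over 20 divisions that share arrays, 1393 of 1405 joint calls had opposite signs. Of the probes changed in one part, a median of 88.6% had an interaction estimate of opposite sign in the other (range 66.2 to 98.3). A further 75 had changed only between FGF21KO_UCP1tg and FGF21KO, and 59 in neither of these comparisons. A set of 27 probes moved in opposite directions, falling in UCP1tg against WT and rising in FGF21KO_UCP1tg against FGF21KO, with median log2 fold changes of -1.06 and 1.39. Independent lists would share 11.9 probes of this kind, and 1 probe moved the other way round where they would share 55.7. Calls in opposite directions all but fix the interaction call, which all 27 had. Their levels varied together within genotypes (median pairwise r = 0.54), so they are not 27 separate observations. When the 10 arrays were left out, 18 of the 27 probes kept the interaction call and 4 kept both changes. That fit uses fewer arrays, so a lost call need not mean a lost change.

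The interaction passed at 172 probes without the 10 arrays, 64 positive and 108 negative, of which 136 were also called with all arrays. Over the 529 probes called with all arrays, the median size was 0.825 with all arrays and 0.774 without the 10, and 100% kept their sign. These probes were chosen with the 10 arrays included, so the sizes are descriptive. Random removals left a median of 135, with as few as 172 in 56 of 100 draws. The count was 331 without FGF21KO 4, 872 without UCP1tg 5, 1044 without UCP1tg 7 and 934 without FGF21KO_UCP1tg 7. Quantile normalization gave 1164, array weights 1297 and pairs of consecutive replicate numbers as a block 1118. The first component as a covariate gave 1302, of which 894 were positive and 408 negative, so the balance of signs was not stable.

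Some probes were called in the same direction for the transgene in both FGF21 backgrounds, an overlap that was not tested. Of the probes that fell in UCP1tg against WT, 218 also fell in FGF21KO_UCP1tg against FGF21KO, where independent lists would share 36.5. For the rises the overlap was 75 against 18.2. In opposite directions, 27 probes were shared against 11.9 and 1 against 55.7. Probes vary together, and the 10 arrays of the first component lie unequally between the genotypes of both comparisons, so the independent-list values are only a rough guide. The overlaps were not recomputed without those arrays. Probe 48216 was 13.85 ± 0.511 in FGF21KO_UCP1tg and 15.17 ± 0.471 in FGF21KO (log2 level, SD, n = 10), and there it fell by 1.31 ± 0.23 (SE, limma adjusted p = 0.00102). Probe 6844 showed a log2 difference of 0.43 ± 0.724 in the same comparison (limma adjusted p = 0.783).

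Across all probes the log2 fold changes of the transgene with and without FGF21, which share no array, had a Pearson r of 0.291 (jackknife SE 0.219 over arrays) and a Spearman rho of 0.209. Across the 4376 probes called in either comparison these were 0.406 and 0.453. Probes are not independent replicates and no p is given. The share of the transgene effect kept without FGF21, over all probes, was 0.41 (jackknife SE 0.299), so the average share is poorly fixed by these arrays. To compare sizes without favouring probes picked for a large effect, 1000 probes were chosen in one part of the UCP1tg and WT arrays and measured in the other, over 20 random divisions. Probes that rose had a mean change of 0.72 with FGF21 and 0.20 without it, and the median share kept was 25.0% (range 16.1 to 56.9 over the divisions). Probes that fell changed by -0.53 with FGF21 and by -0.28 without it, and the median share kept was 52.1% (range 21.5 to 136). Without FGF21, a median of 81.4% of the probes that rose and 78.3% of those that fell kept their direction. With FGF21 these were 97.8% and 92.2%. Without the 10 arrays apart on the first component, the median share kept was 31.7% for rises (range 22.1 to 51.4) and 61.7% for falls (range 12.2 to 107.9). These divisions share arrays, so their range is not a confidence interval.

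**Figure D4:**
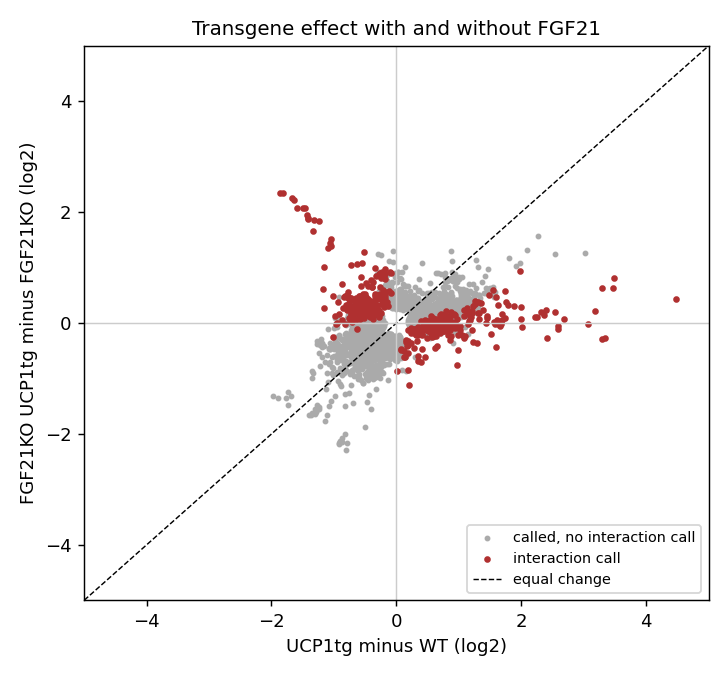
Log2 fold change of UCP1tg minus WT (horizontal axis) against FGF21KO_UCP1tg minus FGF21KO (vertical axis) for the 4376 probes called in either comparison; each point is a probe, red points passed the interaction test and the dashed line marks equal change. Many of the probes with the largest rises in UCP1tg lie near 0 on the vertical axis, such as probe 6844 at 4.49 and 0.43.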

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

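The tests of mixed tissue, of signal range in the 10 arrays and in the interaction, of the interaction within the other 30 arrays and of the replicate numbers were chosen after the results were seen. The tests of array regions, of other groupings of the arrays, of random removals and of the share kept without the 10 arrays were set before their values were computed.

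Among the named probes and array summaries, 5 of 100 groups of 10 arrays held a value far from the rest, which is what a rate of about 1 in 20 gives by chance. Probe 36914 was at 8.08 in WT 4, with the nearest other WT array at 7.41. Probe 37215 was at 10.3 in FGF21KO 4 against 8.67 in the nearest array. Probe 17264 was at 15.53 in FGF21KO 1 against 13.4. Probe 32151 was at 8.17 in UCP1tg 2 against 6.99. Probe 41199 was at 12.17 in FGF21KO_UCP1tg 10, below the nearest array at 12.93. All are log2 levels.

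The effect of the transgene differed between mice with and without FGF21 at 529 probes. Among 100 assignments of the FGF21 genotype within each transgene status, 1 gave as many, the real one, and the highest other gave 1 probe. The other assignments mix UCP1tg with FGF21KO_UCP1tg arrays, which differed at 2586 probes, and this widens the spread within the mixed groups. They argue against an arbitrary FGF21 grouping, but do not separate an interaction from any other effect of FGF21. The 10 arrays on the first component as the whole source are argued against, since the other 30 arrays alone gave 172 probes by limma. Of 100 assignments of those 30 arrays, 1 gave as many, the real one, with 1 probe in the highest other, under the same limit. With all arrays, the interaction estimates did correlate with the difference between the 10 arrays and the rest (Pearson r = 0.374 across probes, which are not independent replicates). Unequal signal ranges are argued against by the 1164 probes called after quantile normalization. It stays open how far the 10 arrays shift the average, because the share of the transgene effect kept was 0.346 without them (jackknife SE 0.196) and 0.41 with all arrays (jackknife SE 0.299), which leaves shares above 0.6 possible.

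For the single comparisons, UCP1tg against WT gave 3216 probes and 2 of 100 groupings gave as many, the real one included. This lies under the share of 0.05 set beforehand, but 100 groupings fix such a share only roughly. The highest other gave 7282 and 7 of the others gave any call, so chance is argued against and not excluded. The grouping with 7282 correlated with the first component (r = 0.685) and with the SD of the arrays (r = -0.618), which points to structure among the samples other than genotype. For FGF21KO against WT all 100 groupings gave at least 0 probes, as they must, and the highest other gave 1843. For FGF21KO_UCP1tg against FGF21KO 1 of 100 gave as many as 1481, with 0 in the highest other. For FGF21KO_UCP1tg against UCP1tg 1 of 100 gave as many as 2586, with 1 in the highest other. Chance is argued against for both.

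For the 10 arrays apart on the first component, 2 of WT, 4 of UCP1tg and 4 of FGF21KO_UCP1tg, a defect in one region of the array is argued against, since loadings of features one array row apart correlated at 0.0125. For the signal range of these arrays the first test, a Spearman correlation of -0.281 between score and array SD, decided nothing, because it lay within its spread of the bound and the arrays fall into separate groups. A second test, put in its place once that value was known, argues against it, as 99.2% of the probes at least 2-fold higher in these arrays stayed so after quantile normalization. RNA of another tissue in the dissected depot stays open, since the rise exceeded by 1 probe in 1000 was 3.141 times the fall exceeded by 1 in 1000, a ratio that restates the asymmetry seen in these arrays and adds no support. Genotype stays open too (Fisher's exact test over the 4 genotypes, two-sided p = 0.112). On first-component scores, FGF21KO_UCP1tg minus FGF21KO was 0.138 (permutation p = 0.02, or 0.08 adjusted over 20 tests). The other comparisons on this component had adjusted permutation p values of 0.368 or more.

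When the 10 arrays were left out, FGF21KO_UCP1tg against FGF21KO went from 1481 to 284 probes. Removing random arrays in the same numbers per genotype gave as few in 60 of 100 draws, with a median of 238.5, so the loss of arrays alone could give this drop.

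The spread of values within an array followed the replicate number. Numbers held 78.1% of the variance of the array SD (permutation p = 1e-05, the smallest the resampling can give) and genotypes 3.52%, with a permutation p of 0.727 that does not exclude a genotype difference. Pairing consecutive numbers ranked 9 of all 945 pairings for closeness (exact p = 0.00952), with mean SDs of 2.329, 2.212, 2.331, 2.127 and 2.216 from the pair 1 and 2 to the pair 9 and 10. Same-numbered arrays may therefore have been handled together, possibly as 5 sets of 8 that each hold all genotypes, which the labels do not state. Within these 5 sets between 89.7% and 99.6% of the UCP1tg against WT probes and between 85.1% and 100% of the interaction probes kept their direction, a description of probes chosen on the same arrays.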

How the results depend on the processing

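Fits without the 10 arrays or a single array, with the first component as covariate and with consecutive numbers as a block were chosen after the results were seen. The replicate number as a block gave 2884 probes for FGF21KO_UCP1tg against FGF21KO, 1142 for the interaction and 23 for FGF21KO_UCP1tg against WT, and stayed within 1.5 times elsewhere. With the genotype means removed, same-numbered arrays correlated above 0.1 in 37 of 60 pairs (median r 0.156, other numbers -0.0116), and 13 matched their own number best where chance gives 6. This hints at a shared factor, but not every pair passed 0.1, as pairing was set to require. Consecutive numbers as a block gave 2662 for FGF21KO_UCP1tg against FGF21KO and 1118 for the interaction. Quantile normalization gave 11 probes for FGF21KO against WT, 1164 for the interaction and 22 for FGF21KO_UCP1tg against WT. Array weights gave 59, 1297 and 25 for these, and 6437 for FGF21KO_UCP1tg against FGF21KO. Only the genotypes compared gave 1942 for UCP1tg against WT. A minimum of 1.5-fold gave 1113 for UCP1tg against WT, 381 for FGF21KO_UCP1tg against FGF21KO and 857 for FGF21KO_UCP1tg against UCP1tg, fewer by construction. Without the 10 arrays the counts were 6 for FGF21KO against WT, 284 for FGF21KO_UCP1tg against FGF21KO, 1168 for FGF21KO_UCP1tg against UCP1tg, 172 for the interaction and 4 for FGF21KO_UCP1tg against WT. The first component as covariate gave 5253 for UCP1tg against WT, 18 for FGF21KO against WT, 4430 for FGF21KO_UCP1tg against UCP1tg, 1302 for the interaction and 111 for FGF21KO_UCP1tg against WT. Leaving out 1 array gave 0 to 12 for FGF21KO against WT, 548 to 2511 for FGF21KO_UCP1tg against FGF21KO, 331 to 1044 for the interaction, 1 to 31 for FGF21KO_UCP1tg against WT, 2564 to 3586 for UCP1tg against WT and 1769 to 3461 for FGF21KO_UCP1tg against UCP1tg. Random removals were run only beside the removal of the 10 arrays. For the other shifts, those with a single array left out included, the cause was not tested, apart from the 1.5-fold minimum. Trend and robust options and the filter on dim probes kept every count within 1.5 times. Median centring moves nothing here, as the arrays share a median. The correlation and the share of the transgene effect kept were rerun with quantile normalization, median centring, the filter on dim probes and without the 10 arrays. They stayed within their jackknife SEs of 0.219 and 0.299, which are so wide that a sizeable shift would have stayed within them too. Blocks, array weights and the first component as covariate were not applied to them. The alternatives by gene, by lymphocyte and muscle genes, by slide and by background correction were not run. Signal over background was not used here, so which low levels lie near background is unknown.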

Other observations

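The comparison here was added after the results were seen. FGF21KO_UCP1tg differed from WT at 9 of 38916 probes by limma, 3 higher and 6 lower, with 2180 probes at an unadjusted p under 0.05. The count was 111 with the first component as covariate (73 higher, 38 lower), 25 with array weights, 23 with the replicate number as a block and 22 after quantile normalization. A small count does not show that the genotypes are alike, as probe 44673 had a log2 difference of -1.93 ± 0.452 (SE, limma adjusted p = 0.12) and probe 39540 one of 1.71 ± 0.546 (limma adjusted p = 0.481). Probe 35351 rose by 0.73 ± 0.129 (log2, SE, limma adjusted p = 0.0264) and probe 31124 by 0.82 ± 0.16 (limma adjusted p = 0.0349). Probe 19868 went from 12.13 ± 0.561 in WT to 10.75 ± 0.398 in FGF21KO_UCP1tg (SD, n = 10), a log2 fold change of -1.38 ± 0.204 (limma adjusted p = 0.00151), and stood at 11.3 in UCP1tg. Probe 32151 fell by 1.33 ± 0.247 (limma adjusted p = 0.0276).

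This count is small and moves with single arrays. It was 5 without WT 1, 1 without WT 2, 2 without WT 3, 4 without WT 4, 31 without WT 6, 1 without WT 7 and 23 without WT 10. Within FGF21KO_UCP1tg it was 1 without array 1, 14 without 2, 4 without 4, 1 without 5, 1 without 6 and 4 without 7. Without the 10 arrays apart on the first component it was 4, of which 2 were also called with all arrays. The limma adjusted p then lay at 0.00654 for probe 19868, 0.0132 for probe 35351, 0.222 for probe 31124 and 0.332 for probe 32151. The log2 fold changes of probes 31124 and 32151 were then 0.84 and -1.26, close to those over all arrays, so with fewer arrays the calls ended without a clear loss of size.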
